A study of Mus musculus with 45 samples.

How the data were processed

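The series measured RNA of microglia, mMΦ and pvMΦ by single-read sequencing. Per the labels' protocols, cells were sorted from mouse brains into an RNA-stabilising reagent, RNA was taken with a micro-scale column kit, cDNA was made with a full-length, unstranded ultra-low-input kit, and libraries with a transposase kit. Gene counts were made by the authors and deposited as 1 table of integers; per the submitters' processing notes, reads were demultiplexed with bcl2fastq 2.18, aligned with STAR 2.7.8a and counted per gene with featureCounts 2.0.2. The genome build, the annotation and the strand setting are not given in the sources used here, and counts of genes that overlap on opposite strands are uncertain because the kit keeps no strand. The table held 53546 gene symbols, of which 35253 had a count, and all its 45 columns were used. Total counts ran from 9898257 to 26428491 per library (median 20890365). Libraries of a group differed by far more than counting error, with a chi-square per degree of freedom of 21.6 to 411 between them, so scatter between libraries, whether of mice, input or preparation, and not counting error set the precision of most genes.

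Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 17064, and scaled by TMM. CPM values use the TMM-scaled totals. The test was the quasi-likelihood F test of edgeR 4.0.16 (robust) in R 4.3.3 on all 45 libraries, with 1 coefficient per group of population and age and 1 for sequencing batch S276. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within each of 27 contrasts: mMΦ against microglia at 5 ages, pvMΦ against microglia and against mMΦ at 3 ages each, the whole age span in each population, 10 steps between successive ages, and 3 differences of changes. These contrasts, the test, the other settings to try and the rule for naming genes were fixed before the data were examined. For each contrast the 12 genes with the largest log2 fold change in each direction (5 for steps) are named from the top, if called, at a mean of at least 5 CPM in a group compared and without overlap between the libraries of the 2 groups. Overlap was not asked for in the differences of changes. Gene models without a name, mitochondrial, ribosomal protein and sex-chromosome marker genes were left out of the naming. Genes called at all 5 ages are named by the smallest of their 5 fold changes. As examples of a list, up to 4 called members with the largest change and up to 2 uncalled members with the highest mean are named, and 16 genes known from these cells are followed throughout. Where a group had no counts at all, a bound is given instead of the fitted fold change, from 3 counts over the group.

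The 33 gene lists (19 of gene programmes, 13 of other cell types, 1 of sex-linked genes) were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over all lists and contrasts, and again with an estimated correlation. Of these tests 361 passed (180 with the latter). Members called are also given after adjustment over the list alone.

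Settings tried as chosen beforehand were size factors of DESeq2 1.42.0 in place of TMM, no low-count filter, the Wald test of DESeq2, no batch term, batch S232 only, the replicate number as a block, the compared groups only, and leaving out each library in turn. Limma voomWithQualityWeights, and a fit without the 3 libraries that stand apart, were added after the data were seen. The fits were tested on simulated data with 67, 67 and 66 genes changed 2-, 4- and 8-fold. Dispersion was the same in all groups (chosen beforehand) or each group's own (added after the scatter by age was seen). With the latter, edgeR recovered 20 of 66 8-fold changes at E14.5 and 37 of 66 at P56 between mMΦ and microglia. Many were thus missed, and genes not called are not shown to be equal. False were 7.8 to 58.7% of limma calls, 0 to 11.1% of those of edgeR on the compared groups and 0 to 63.6% on all libraries, the fit used here. With the same dispersion this fit had 0 to 9.6%. Such shares depend on how many genes change and need not hold for the real lists. Libraries were also regrouped at random, in up to 100 distinct splits per comparison.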

Results

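Gene expression was measured by bulk RNA sequencing in 3 macrophage populations sorted from brains of mice that carry GFP in 1 allele of Cx3cr1: macrophages of the meninges (mMΦ), macrophages of the perivascular space (pvMΦ) and microglia of the parenchyma. Embryos at E14.5 and pups or adults at P3, P10, P21 and P56 were sampled, with pvMΦ sampled only from P10. The 45 libraries fell into 13 groups of 3 to 5, namely 19 of microglia (3, 3, 3, 5 and 5 by age), 15 of mMΦ (3 at each age) and 11 of pvMΦ (3, 4 and 4), and the replicates were individual mice per the series' design. Levels are given in CPM after TMM scaling, mean ± SD over the libraries of a group, and differences as log2 fold changes ± SE from edgeR. Genes named for a comparison of groups were called at an adjusted p under 0.05 with no overlap between the libraries compared, unless they are given as members of a list or as 1 of the 16 genes followed throughout.

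The genes by which these cells are usually recognised set the populations far apart in adult mice (5 microglia, 3 mMΦ and 4 pvMΦ libraries). At P56, P2ry12, a purinergic receptor of microglia, was at 12646 ± 1547 CPM in microglia, 350 ± 26.1 in mMΦ and 1760 ± 721 in pvMΦ. Tmem119 was at 6177 ± 1814, 103 ± 32.3 and 819 ± 406 CPM, and Siglech, a lectin of microglia, at 3689 ± 915, 197 ± 34.7 and 752 ± 215. Sall1, a transcription factor of microglial identity, was at 376 ± 111 CPM in microglia and 0.928 ± 0.806 in mMΦ, with pvMΦ between them at 34 ± 23.5. The border macrophage genes ran the other way. Mrc1, the mannose receptor, was at 8.11 ± 4.27 CPM in microglia, 2954 ± 208 in mMΦ and 2579 ± 563 in pvMΦ, and the hyaluronan receptor gene Lyve1 at 0.724 ± 0.544, 1278 ± 117 and 1067 ± 281. The chemokine gene Pf4 was at 2.02 ± 1.33, 3431 ± 1263 and 3349 ± 1389 CPM, and Ms4a7 at 1.05 ± 0.724, 1926 ± 310 and 2209 ± 797. Cx3cr1, whose locus carries the reporter, was detected in all 3 populations at 3367 ± 766, 479 ± 152 and 869 ± 430 CPM, and the transcription factor gene Maf at 459 ± 148, 626 ± 105 and 722 ± 274.

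**Figure D1:**
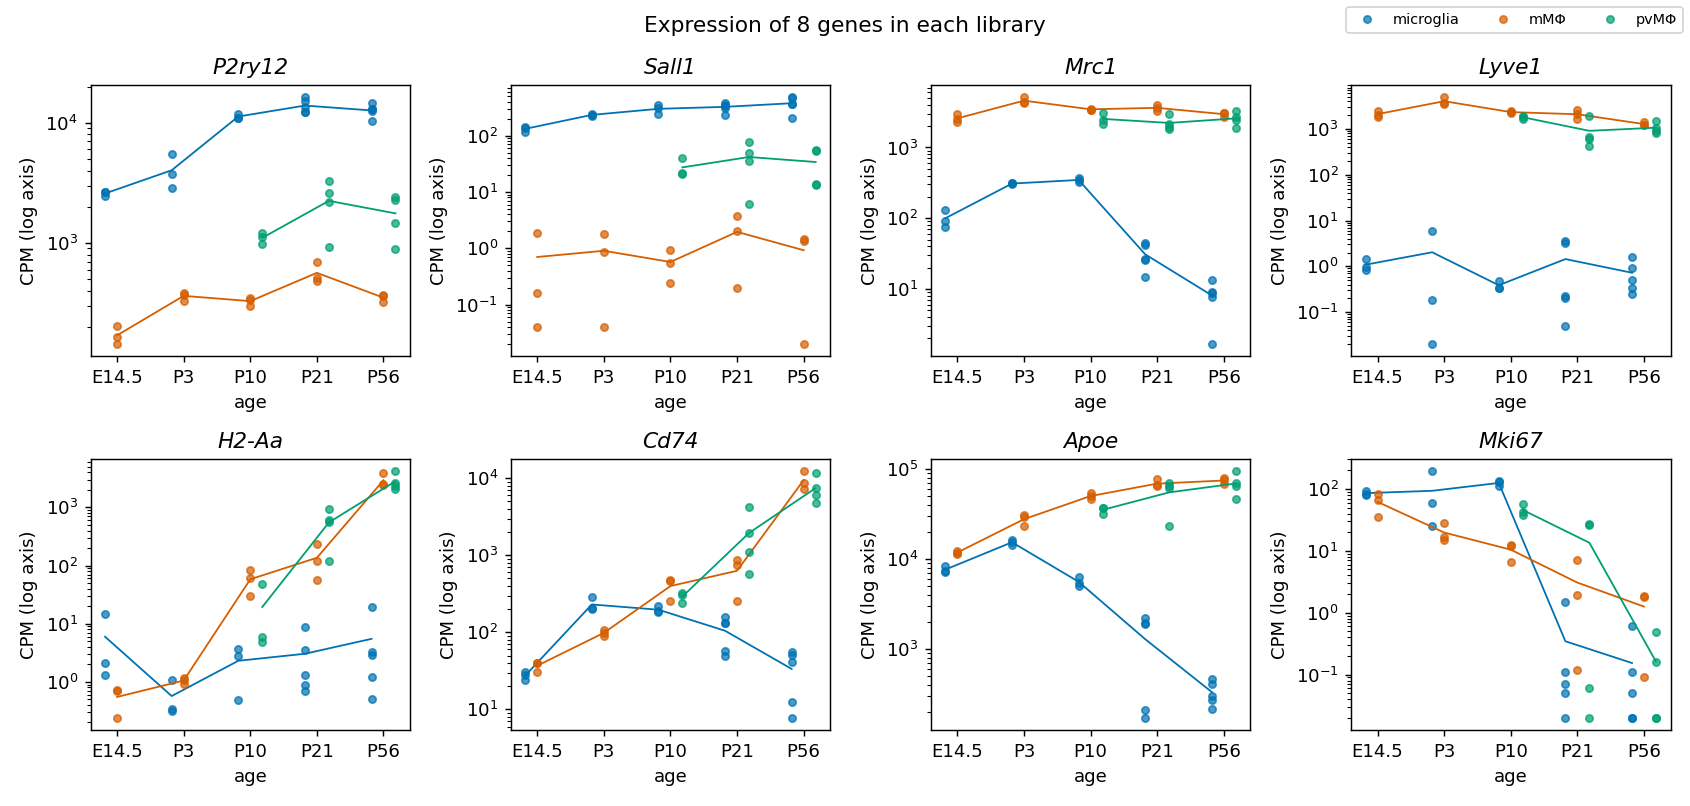
CPM (log axes) of 8 genes in each library against age, with microglia in blue, mMΦ in orange, pvMΦ in green and lines through the group means; values under 0.02 CPM are drawn at 0.02. P2ry12 and Sall1 were highest in microglia, Mrc1 and Lyve1 in mMΦ and pvMΦ, H2-Aa and Cd74 climbed in mMΦ and pvMΦ to means of 2932 and 9437 CPM in mMΦ at P56, Apoe parted to 330 CPM in microglia and 74469 in mMΦ, and Mki67 ended at 0.154 CPM in microglia at P56.

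The libraries themselves changed with age, and this bears on every comparison. At equal thinned totals microglia yielded 16131 detected genes on average at E14.5 and 13918 at P56, mMΦ 16229 and 13471, and pvMΦ 15839 at P10 and 13159 at P56. The scatter between replicates grew as well, with an edgeR common dispersion of 0.27 in microglia at E14.5 and 1.63 at P56, 0.28 and 1.61 in mMΦ, and 0.43 at P10 and 2.26 at P56 in pvMΦ. Microglia P56 replicate 2, which also had the lowest total, pvMΦ P21 replicate 1 and pvMΦ P56 replicate 3 stood apart from all others on principal component 4 or 5, by 213.7, 205.5 and -251.3 against a limit of 100 set after the data were seen. On component 6 pvMΦ P56 replicate 2 stood at 231.2, but it was not counted with these 3. Of the 45 libraries, 7 came from sequencing batch S276, all of them microglia or pvMΦ from P3 onward, and the batch term of the model passed the test in 1098 genes. By Xist and Y-linked transcripts, replicates 1 and 2 of microglia and of mMΦ at E14.5 and replicates 3 and 4 of microglia at P3 were of female type, microglia P21 replicate 1 held both (Xist 121.19 and Y-linked genes 74.38 CPM), and the remaining libraries were of male type. Comparisons of E14.5 with later ages (except microglia at P3, of the same mix), of the populations at P3, and of microglia at P10 with P3 therefore also compare sexes.

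Microglia and meningeal macrophages were compared at each of the 5 ages to ask which genes set the populations apart from before birth into adulthood. A core of 255 genes was called at all 5 ages in the same direction, 146 higher in mMΦ and 109 higher in microglia, where independent lists of these sizes would share 0.0011 and 0.00019. Ranked by the smallest of the 5 fold changes, the mMΦ side was led by Lyve1, Slc7a13, Fpr1, Pf4, Gfra2, Bmp2, Clec10a, F13a1, Foxred2, Cxcl1, Cd163 and Aspa. Lyve1 had log2 fold changes of 10.92, 10.81, 12.54, 10.21 and 10.31 from E14.5 to P56 and Pf4 of 8.59, 9.35, 10.24, 10.01 and 10.76. On the microglial side stood Hspb3, Tmc7, Sall1, Npnt, Chad, Il7r, Adgrg1, Spint1, Sparc, Tmem119, Serpine2 and Gal3st4. Sall1 had log2 fold changes of -7.50, -7.89, -9.03, -7.27 and -8.46, Tmem119 of -5.05, -4.98, -6.96, -5.39 and -5.67, and Sparc, a secreted matrix protein gene, of -7.58, -6.60, -6.77, -5.10 and -6.23. Of the 415 genes called at E14.5, 324 were also called at P56 in the same direction and 6 in the opposite direction. With limma voom and library weights the core held 620 genes and with the DESeq2 Wald test 428, and with S232 libraries alone 242.

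Already at E14.5 the border and microglial programmes were divided. Highest in mMΦ over microglia (n = 3 each) were Lyve1, Fpr1, Plekhg3, Ptprk, F13a1, Ahr, Gfra2, Aspa, Pf4, Bmp2, Tlr8 and Clec10a. Lyve1 was at 2109 ± 320 against 1.08 ± 0.347 CPM (log2 fold change 10.92 ± 1.04, adjusted p = 1.3e-09). F13a1, a subunit of clotting factor XIII, was at 5454 ± 495 against 9.38 ± 7.12 CPM, Pf4 at 2322 ± 150 against 6 ± 1.23, and the growth factor gene Bmp2 at 188 ± 22.5 against 0.602 ± 0.762. Fpr1, a formyl peptide receptor gene, had no counts in microglia and was at least 180-fold higher in mMΦ. Highest in microglia were Chst1, B3galt5, Plxdc1, Hspb3, Mrc2, Sall3, Spint1, Tmem100, Adgrg1, Tlr12, Tmc7 and Serpine2. Chst1 and B3galt5, genes of enzymes that build glycan chains, had no counts in mMΦ and were at least 466-fold and 345-fold lower there. Like all such bounds here, these floors rest on 3 counts over the group and cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Spint1, a protease inhibitor gene, was at 0.148 ± 0.256 against 140 ± 20.2 CPM, the adhesion receptor gene Adgrg1 at 0.118 ± 0.14 against 75 ± 23.9, and Serpine2 at 4.3 ± 1.59 against 1316 ± 76.7.

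Among border macrophage markers at E14.5 27 of 30 were higher, 0 lower and 3 not called (29 and 0 adjusted over the list alone, camera adjusted p = 1.5e-93). Of the microglia markers 0 of 24 were higher, 21 lower and 3 not called (0 and 23 adjusted over the list alone, camera adjusted p = 3.4e-81). Olfml3 (-8.11 ± 0.46) and Sparc (-7.58 ± 0.56) were among them, while Csf1r, the growth factor receptor gene both populations need, was at 4059 ± 99.1 against 4897 ± 942 CPM and not called. In the interferon response list 6 of 30 were higher, 0 lower and 24 not called (14 and 0 adjusted over the list alone, camera adjusted p = 6.2e-14). Ifi207 (3.65 ± 0.88), Ifi27l2a and Rtp4 were examples. Glycolysis genes were lower in mMΦ, with Ldhb at 8.12 ± 1.58 against 251 ± 44.3 CPM. In that list 0 of 23 were higher, 6 lower and 17 not called (0 and 9 adjusted over the list alone, camera adjusted p = 4.1e-07). MHC class II genes were also lower at this age, where 0 of 11 were higher, 3 lower and 8 not called (0 and 6 adjusted over the list alone, camera adjusted p = 1.1e-08). The peptide loading gene H2-DMa (-3.78 ± 0.33), the chain gene H2-Ab1 and H2-DMb1 were among these. In the lysosome list 1 of 37 was higher, 8 lower and 28 not called (1 and 13 adjusted over the list alone, camera adjusted p = 6.5e-08, adjusted p = 0.086 with an estimated correlation). Ctss (-2.51 ± 0.23) and Ctsd were among them. The TGF-beta receptor gene Tgfbr1 was at 71 ± 9.72 against 582 ± 128 CPM (-3.04 ± 0.49). Markers of erythroid cells summed to 432 ± 378 CPM in mMΦ (868.61 in replicate 2, 215 and 211.22 in the others) and 123 ± 38 in microglia.

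After birth the populations stayed apart. At P3 (n = 3 each) the largest differences towards mMΦ were in Cmah, which makes N-glycolylneuraminic acid, Slc25a24 and Slc10a6, all without counts in microglia and at least 1320-fold, 619-fold and 239-fold higher. The haemoglobin scavenger receptor gene Cd163 followed (920 ± 56.2 against 0.126 ± 0.102 CPM, log2 fold change 13.22 ± 0.72). Towards microglia they were in Itgax, Cst7 and Hspb3, at least 772-fold, 339-fold and 470-fold lower in mMΦ. Itgax and Cst7 are known from microglia of the growing white matter and were at 31.4 ± 18.4 and 13.8 ± 11.6 CPM in microglia. At P10 (n = 3 each) Serpinb8, Cd209g and Gypc led, each without counts in microglia and at least 3170-fold, 1690-fold and 1110-fold higher in mMΦ, followed by Bmp2 (12.98 ± 1.21), Thbd and the lectin gene Clec4n (757 ± 80.3 against 0.105 ± 0.0615 CPM). Spint1, Kcnd1 and Slco4a1 led towards microglia, at least 2100-fold, 839-fold and 683-fold lower in mMΦ. MHC class II genes were still lower in mMΦ at P3, where 0 of 11 were higher, 4 lower and 7 not called (0 and 6 adjusted over the list alone, camera adjusted p = 0.00015). Interferon response genes stood higher in mMΦ at P3, where 10 of 30 were higher, 0 lower and 20 not called (15 and 0 adjusted over the list alone, camera adjusted p = 5.4e-13). At P10, 12 of 30 were higher, 0 lower and 18 not called (17 and 0 adjusted over the list alone, camera adjusted p = 5e-12). At P10, for immediate early and dissociation genes, 17 of 34 were higher, 0 lower and 17 not called (24 and 0 adjusted over the list alone, camera adjusted p = 8.3e-14, adjusted p = 0.1 with an estimated correlation). Markers of fibroblasts and leptomeningeal cells moved with the mMΦ side at both ages. At P3, 9 of 20 were higher, 0 lower and 11 not called (14 and 1 adjusted over the list alone, camera adjusted p = 2.9e-16). At P10, 11 of 20 were higher, 0 lower and 9 not called (16 and 0 adjusted over the list alone, camera adjusted p = 1.9e-11). Their summed levels in mMΦ were 306 ± 32.5 and 310 ± 157 CPM.

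By P56 the mMΦ side held scavenger, lipid and antigen presentation genes at high levels. At P21 (3 mMΦ and 5 microglia libraries) the largest differences were in Kcnk5, Ms4a14, Slc27a6 and Wdr19, without counts in microglia, and in Ms4a4a (681 ± 260 against 0.246 ± 0.265 CPM), Ifi203 and Ifi207, with B3galt5, Slco4a1 and Kcnd1 at the microglial end. Oligodendrocyte markers were higher in mMΦ at P21, where 5 of 18 were higher, 0 lower and 13 not called (6 and 0 adjusted over the list alone, camera adjusted p = 0.003). Their sum was 909 ± 568 CPM against 184 ± 19.9, with 1556.43 in mMΦ replicate 1 and 677.6 and 492.96 in the others. At P56 (3 and 5 libraries) Iqcn, Ttr, Fpr1, Bmp2, AA467197, Calml4, Timd4, Plekhg3, Adcy4, Ifi208, Cd209a and Mx1 led. Timd4, a receptor for phosphatidylserine on dying cells, was at 186 ± 21.6 against 0.0114 ± 0.0256 CPM, and Bmp2 at 166 ± 25.3 against 0.0114 ± 0.0256. Ttr and Calml4 are transcripts of the choroid plexus epithelium, and Ttr was at 263 ± 246 CPM in mMΦ. Upk1b, Adora3, Mlph, Hspb3, Mymk and Slco4a1 led towards microglia, and the first 3 were at least 4070-fold, 2560-fold and 1690-fold lower in mMΦ. Apoe, the lipoprotein gene, was at 74469 ± 6033 against 330 ± 103 CPM (7.31 ± 0.47, adjusted p = 2.5e-14), and H2-Aa at 2932 ± 852 against 5.5 ± 7.96 (8.95 ± 1.07).

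Among border macrophage markers at P56 29 of 30 were higher, 0 lower and 1 not called (30 and 0 adjusted over the list alone, camera adjusted p = 1.9e-71). Cbr2 (11.75 ± 0.72), Cd209b and Cd163 were the largest, while the iron exporter gene Slc40a1 was at 468 ± 131 against 346 ± 142 CPM and not called. Of the microglia markers 0 of 24 were higher, 23 lower and 1 not called (0 and 24 adjusted over the list alone, camera adjusted p = 3.3e-47), Sall1 among them (-8.46 ± 1.18). In MHC class II 5 of 11 were higher, 1 lower and 5 not called (5 and 2 adjusted over the list alone, camera adjusted p = 0.0021). H2-Aa, Ciita and H2-Eb1 were higher and H2-Oa (-8.66 ± 1.64) lower. For the interferon response 19 of 30 were higher, 0 lower and 11 not called (22 and 0 adjusted over the list alone, camera adjusted p = 1.8e-19). Mx1, Oas2 (11.44 ± 1.99) and Ifi207 (8.25 ± 0.90) were examples. Genes of amoeboid and lipid-associated microglia were mostly higher in mMΦ at this age, where 13 of 25 were higher, 2 lower and 10 not called (14 and 3 adjusted over the list alone, camera adjusted p = 4.8e-08). Gpx3, Ch25h, the growth factor gene Igf1 (7.62 ± 0.59) and Apoe were among these. In cholesterol synthesis 9 of 23 were higher, 0 lower and 14 not called (10 and 0 adjusted over the list alone, camera adjusted p = 4.5e-07). Stard4 was among them. In cholesterol efflux and lipid transport 12 of 23 were higher, 3 lower and 8 not called (13 and 3 adjusted over the list alone, camera adjusted p = 5.1e-05). Pparg, the scavenger receptor genes Msr1 (9.37 ± 0.87) and Cd36 (9.22 ± 0.75), and Pltp were examples. Of chemokines and cytokines 16 of 30 were higher, 0 lower and 14 not called (16 and 2 adjusted over the list alone, camera adjusted p = 1.2e-12). Cxcl1 and Cxcl2 (9.84 ± 0.94) were among these. Immediate early and dissociation genes moved with the populations, as 28 of 34 were higher, 0 lower and 6 not called (30 and 1 adjusted over the list alone, camera adjusted p = 6.4e-25). Their summed levels were 62218 ± 11200 CPM in mMΦ and 7697 ± 1846 in microglia, and these transcripts are known to respond to tissue handling. Markers of other cells were also higher in mMΦ. Of ependymal and choroid plexus markers 6 of 11 were higher, 0 lower and 5 not called (9 and 0 adjusted over the list alone, camera adjusted p = 0.00015). Of fibroblast and leptomeningeal markers 11 of 20 were higher, 1 lower and 8 not called (14 and 1 adjusted over the list alone, camera adjusted p = 9.2e-05). Of monocyte markers 4 of 10 were higher, 1 lower and 5 not called (6 and 1 adjusted over the list alone, camera adjusted p = 0.0015). Ccr2 was at 101 ± 39.4 against 4.13 ± 5.06 CPM.

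In all, edgeR called 415 genes between mMΦ and microglia at E14.5 (224 higher and 191 lower in mMΦ), 780 at P3 (415 and 365), 1121 at P10 (656 and 465), 1743 at P21 (1159 and 584) and 2198 at P56 (1346 and 852). This order by age depended on the fit, since limma voom with library weights gave 2772, 1839, 3884, 2240 and 2038 genes, edgeR on the compared groups alone 2432, 1354, 2927, 1224 and 711, and the DESeq2 Wald test 931, 1702, 2058, 2806 and 3617. The spread of fold changes shared by disjoint pairs of libraries, to which scatter confined to a library adds nothing, widened from 1.11 at E14.5 to 1.39, 1.62, 1.74 and 1.83 at P56 over 6426 genes. Within batch S232 the counts were 414, 542, 1129, 1228 and 1890, and single libraries moved the count over 1.5 times at P3 (507 without microglia P3 replicate 2) and at P10 (721 without microglia P10 replicate 2). In simulation with each group's own dispersion and few changed genes, 6 of 47 calls at P21, 34 of 97 at P56 and 0 of 24 at E14.5 were false (16302, 16343 and 16352 genes).

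**Figure D2:**
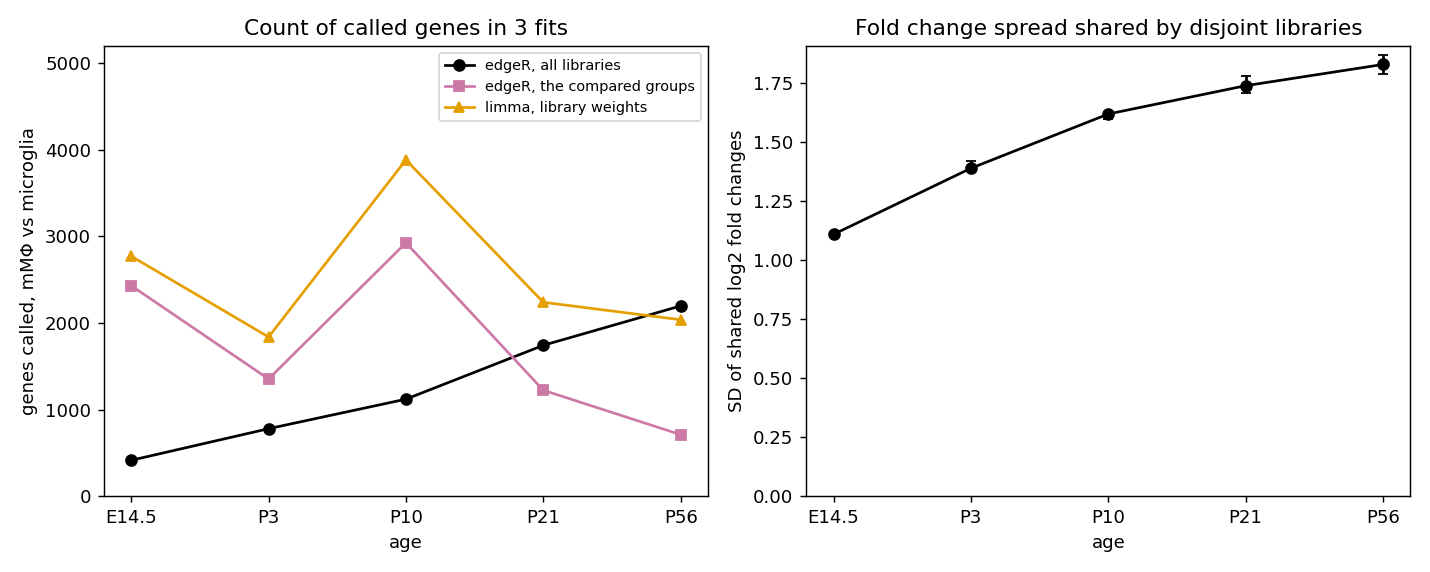
Genes called between mMΦ and microglia at each age (left, count) by edgeR on all libraries, edgeR on the compared groups and limma with library weights, and the SD of log2 fold changes shared by disjoint libraries (right, bars: range when 1 library is left out). The counts rose from 415 to 2198 in the first fit and ended lower than they began in the other 2 (711 and 2038 at P56), while the shared SD widened from 1.11 to 1.83.

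Perivascular macrophages were set against microglia to ask what distinguishes these neighbours in the brain at the ages when both were sampled. At P10 (n = 3 each) pvMΦ already carried the border macrophage programme. Serpinb8, Hbb-bs, Lyve1, Gypc, Thbd, Fpr1, Cd40 and Retnla led, with Lyve1 at 1803 ± 134 against 0.387 ± 0.0863 CPM, Serpinb8 at least 1860-fold higher and Retnla, a secreted protein of alternatively activated macrophages, at 886 ± 487 against 0.232 ± 0.1. The haemoglobin gene Hbb-bs ranked high at 35.6 ± 60.6 CPM. Microglial genes were lower in pvMΦ, with Myo18b (at least 376-fold), Ecscr (-4.15 ± 1.02), Camk2n1, Sparc (980 ± 115 against 13717 ± 725 CPM), Tmem119 (261 ± 24.5 against 3206 ± 86.5), Adgrg1, Slc2a5, Selplg, Serpine2, Siglech and Sall1 (-3.45 ± 0.93) at the far end. At P21 (4 and 5 libraries) Areg, Ms4a4a (11.87 ± 0.98), Slfn1, Slc7a13, Ifi203, Slc25a24, Tlr8 and Ms4a7 (2153 ± 332 against 1.03 ± 0.953 CPM) led, and Slc39a4, Mrgpre and Adtrp had no counts in pvMΦ. At P56 (4 and 5 libraries) Fpr1, Plekhg3, Timd4 (125 ± 51.3 CPM, 12.60 ± 0.96), Bmp2, Foxred2, Cd209a, Napsa and Cd209b led, and Ctnnal1, Zfp951 and Gsg1 were at least 980-fold, 813-fold and 452-fold lower.

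Border macrophage markers were higher in pvMΦ than in microglia. At P10, 29 of 30 were higher, 0 lower and 1 not called (30 and 0 adjusted over the list alone, camera adjusted p = 9.9e-95). At P56, 30 of 30 were higher, 0 lower and 0 not called (30 and 0 adjusted over the list alone, camera adjusted p = 1.2e-84). Microglia markers at P56 gave the reverse, where 0 of 24 were higher, 23 lower and 1 not called (0 and 24 adjusted over the list alone, camera adjusted p = 5.4e-27). Upk1b (-4.30 ± 1.32), Sall1 (-3.43 ± 0.79) and Slc2a5 (-3.22 ± 0.61) were among them. In MHC class II at P56 5 of 11 were higher, 0 lower and 6 not called (5 and 1 adjusted over the list alone, camera adjusted p = 0.00026). H2-Aa was at 2827 ± 955 against 5.5 ± 7.96 CPM and the invariant chain gene Cd74 at 7460 ± 2934 against 33.5 ± 22 (7.71 ± 0.57). For the interferon response at P56 20 of 30 were higher, 0 lower and 10 not called (23 and 0 adjusted over the list alone, camera adjusted p = 6.1e-18). Among amoeboid and lipid-associated genes 13 of 25 were higher, 3 lower and 9 not called (15 and 3 adjusted over the list alone, camera adjusted p = 1.7e-12). Apoe was at 69015 ± 20134 against 330 ± 103 CPM. Of cholesterol efflux and lipid transport genes 10 of 23 were higher, 2 lower and 11 not called (10 and 2 adjusted over the list alone, camera adjusted p = 1e-06). Of chemokines and cytokines 17 of 30 were higher, 0 lower and 13 not called (17 and 2 adjusted over the list alone, camera adjusted p = 6.3e-15). Immediate early and dissociation genes were higher too, as 28 of 34 were higher, 0 lower and 6 not called (30 and 0 adjusted over the list alone, camera adjusted p = 3.4e-26). They summed to 44308 ± 7959 CPM in pvMΦ. Among fibroblast and leptomeningeal markers 7 of 20 were higher, 0 lower and 13 not called (7 and 0 adjusted over the list alone, camera adjusted p = 0.00098, adjusted p = 0.08 with an estimated correlation). EdgeR called 645 genes at P10 (408 higher and 237 lower in pvMΦ), 1610 at P21 (1083 and 527) and 1816 at P56 (1098 and 718). Within batch S232 it called 650, 1093 and 1958, and at P10 423 without microglia P10 replicate 2. Here too the order depended on the fit, since edgeR on the compared groups gave 2166, 891 and 465 genes, limma with library weights 2962, 1675 and 1052 and the DESeq2 Wald test 1394, 2802 and 3507. In simulation with each group's own dispersion 12 of 65 calls at P21 and 103 of 162 at P56 were false (16327 and 16297 genes).

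The 2 border populations were compared with each other to ask what separates perivascular from meningeal macrophages. They differed in fewer genes than either did from microglia at the same age under every setting, and many of the genes higher in pvMΦ were ones abundant in microglia. At P10 (n = 3 each) the largest differences towards pvMΦ were in Spint1 (at least 142-fold), Cdc25c, Brca1, H2-Oa, Sall1 (27.3 ± 10.5 against 0.572 ± 0.352 CPM, 5.58 ± 1.07, adjusted p = 0.0031), Adgrg1, Serpine2 (174 ± 15.5 against 10.1 ± 3.01), Abi3, Slc2a5, Olfml3 (508 ± 3.95 against 45.3 ± 5.4), F11r and Tmem119 (3.34 ± 0.34). Genes lower in pvMΦ at P10 were the metallothionein gene Mt2 (5.49 ± 0.1 against 64.4 ± 31.6 CPM), the heat shock gene Hspa1a, Socs3 (-3.21 ± 0.55), Ifrd1, Ppp1r15a, Sertad1, Ccnl1, Ddit3, Gadd45g, Atf3 (-2.63 ± 0.51), Ier3 and Id2, many of them stress response genes. Of the immediate early and dissociation list 0 of 34 were higher, 14 lower and 20 not called (0 and 30 adjusted over the list alone, camera adjusted p = 1.3e-58). Of the microglia markers 12 of 24 were higher, 0 lower and 12 not called (18 and 0 adjusted over the list alone, camera adjusted p = 4.3e-43). Csf1r (4798 ± 759 against 4805 ± 250 CPM) was not called. At P21 (4 and 3 libraries) Spint1, Sall1 (4.32 ± 0.97), Abcg1, Sparc (2025 ± 1304 against 339 ± 56.9), Tmem119 and Bhlhe41 were higher and Ltbp3, Oip5 and Ier5 lower. At P56 (4 and 3 libraries) Slco4a1, Hspb3 and Upk1b had no counts in mMΦ and were at least 384-fold, 285-fold and 206-fold higher, followed by Angptl7, Mtrf1 and Adgrg1 (9.41 ± 1.02), and Piga, Zfp446 and Bhlhe40 (-10.24 ± 2.01) led the lower side.

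The level of genes abundant in microglia was measured in each pvMΦ library. Of the microglia markers 12 of 24 were higher, 0 lower and 12 not called (17 and 1 adjusted over the list alone, camera adjusted p = 8.2e-20) at P21. At P56, 15 of 24 were higher, 0 lower and 9 not called (19 and 0 adjusted over the list alone, camera adjusted p = 1.6e-29). Genes of at least 100 CPM in microglia and at least 32 times the mMΦ level reached a median 8.78% of their microglia level in pvMΦ at P10 (20 genes), 12.4% at P21 (21 genes) and 11.2% at P56 (26 genes). By library the median was 7.53 to 9.48% at P10, 14, 12.8, 3.17 and 12.7% in replicates 2, 1, 3 and 4 at P21, and 14, 5.9, 0.0421 and 13.3% in replicates 2, 1, 3 and 4 at P56. Of MHC class II genes at P21 1 of 11 was higher, 0 lower and 10 not called (5 and 0 adjusted over the list alone, camera adjusted p = 6.9e-07), and their sum was 8559 CPM in pvMΦ replicate 1, which stood apart, 1294, 2956 and 4139 in the others and 1197 ± 559 in mMΦ. H2-DMa was at 195 ± 102 against 66.2 ± 22.2 CPM. At P56 Cd74 was at 7460 ± 2934 in pvMΦ and 9437 ± 2687 in mMΦ and was not called. Ependymal and choroid plexus markers summed to 11.8 ± 10 CPM in pvMΦ and 316 ± 289 in mMΦ at P56 (645.01 in replicate 2, 199.54 and 102.42 in the others). EdgeR called 93 genes at P10 (37 higher and 56 lower in pvMΦ), 53 at P21 (38 and 15) and 92 at P56 (57 and 35), and within batch S232 110, 53 and 288. Without the libraries that stand apart the count at P56 was 174.

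The calls between the border populations at P21 and P56 did not hold in every fit. With edgeR on the compared groups alone no gene was called, 0 at P21 (534 at an unadjusted p under 0.05) and 0 at P56 (784 unadjusted), microglia markers such as Sall1 included, while limma with library weights called 32 and 17 genes and the DESeq2 Wald test 780 and 1463. In simulated counts with each group's own dispersion 18 of 78 calls at P21 and 65 of 122 at P56 were false (16358 and 16316 genes). Single libraries moved the counts of 93, 53 and 92 genes over 1.5 times. At P10 the count was 53 without mMΦ P10 replicate 2, 60 without replicate 3, 57 without pvMΦ P10 replicate 2 and 60 without replicate 3. At P21 it was 35 without mMΦ P21 replicate 2, 33 without pvMΦ P21 replicate 1 and 145 without replicate 3. At P56 it was 41 without mMΦ P56 replicate 1, 58 without pvMΦ P56 replicate 2 and 398 without replicate 4. At P10 limma gave 893 genes, the Wald test 324, and the compared groups alone 538 and 16 of 23 microglia markers higher in pvMΦ.

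**Figure D3:**
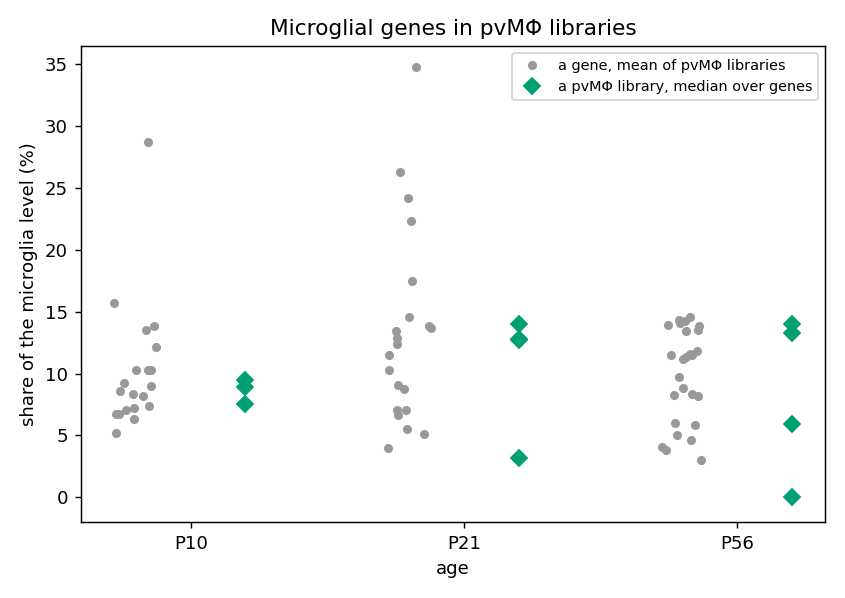
Level in pvMΦ as a share (%) of the microglia level, after subtracting the mMΦ level, for genes abundant in microglia and nearly absent from mMΦ, by age. Grey points are genes (20, 21 and 26), green diamonds are the medians of single pvMΦ libraries, which ran from 7.53 to 9.48% at P10, from 3.17 to 14% at P21 and from 0.0421 to 14% at P56.

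Microglia were followed from E14.5 to P56 to ask how they mature. Transcripts of cell division and of the amoeboid state fell, and those of homeostasis, complement and MHC class I rose. The largest rises (3 libraries at E14.5, 5 at P56) were in Mlph, Enpp5, Slc39a12, Slc5a10, Thrsp, Hlf, Nr3c2, Upk1b, Csmd3 and Sult1a1. Mlph, which links vesicles to myosin, stood at 82.9 ± 30.6 against 0.0317 ± 0.055 CPM, the lipogenic regulator gene Thrsp at 158 ± 79.6 against 0.242 ± 0.419, and Sult1a1, a sulfotransferase gene, at 214 ± 55.1 against 1.06 ± 1.3 (7.68 ± 0.71, adjusted p = 3.6e-10). The largest falls were in Ddias, Stil, Itgal, Tube1, Fancb, Pdlim7, Uhrf1, Sgo1, Rtkn2 and Plk1, most of them genes of DNA replication and mitosis. Stil had no counts at P56 and was at least 994-fold lower, Uhrf1 was at 0.0347 ± 0.0534 against 102 ± 15.1 CPM and Plk1 at 0.0218 ± 0.03 against 85.1 ± 3.87. Cell cycle genes fell as a list, since 0 of 40 were higher, 35 lower and 5 not called (0 and 39 adjusted over the list alone, camera adjusted p = 3.2e-30). Mki67 went from 85.4 ± 6.16 to 0.154 ± 0.257 CPM.

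Of the microglia markers 20 of 24 were higher, 0 lower and 4 not called (21 and 0 adjusted over the list alone, camera adjusted p = 1.1e-27). Cst3 (4.82 ± 0.26), Selplg (4.62 ± 0.40) and Ecscr rose most, whereas Sall1 at 376 ± 111 against 132 ± 11.9 CPM was not called. Among genes of amoeboid and lipid-associated microglia 3 of 25 were higher, 14 lower and 8 not called (3 and 15 adjusted over the list alone, camera adjusted p = 2.5e-08). Gpnmb, Gpx3 (-8.61 ± 0.56), the osteopontin gene Spp1 (3.31 ± 4.41 against 1142 ± 503 CPM) and Fabp5 were among the falls. In the complement and Fc receptor list 12 of 20 were higher, 0 lower and 8 not called (12 and 1 adjusted over the list alone, camera adjusted p = 2.7e-13). Fcgr2b (4.28 ± 0.22), C1qa (2.32 ± 0.12) and C1qb were among these. MHC class I genes rose, as 9 of 15 were higher, 0 lower and 6 not called (11 and 0 adjusted over the list alone, camera adjusted p = 6.5e-11). H2-T23 (2.92 ± 0.27), H2-K1 and B2m were among them. Fetal growth and oncofetal genes fell, where 0 of 16 were higher, 5 lower and 11 not called (1 and 10 adjusted over the list alone, camera adjusted p = 0.00098). Igf2bp3 (-8.31 ± 1.20) and Lin28b, RNA regulators of early development, were examples. In cholesterol efflux and lipid transport 2 of 23 were higher, 11 lower and 10 not called (3 and 12 adjusted over the list alone, camera adjusted p = 0.00033). In cholesterol synthesis 1 of 23 was higher, 6 lower and 16 not called (1 and 11 adjusted over the list alone, camera adjusted p = 7.7e-05). Glycolysis genes fell, as 1 of 23 was higher, 8 lower and 14 not called (1 and 12 adjusted over the list alone, camera adjusted p = 0.00019). Pkm (-2.29 ± 0.18) and Ldha were among these. Lysosomal genes leaned upward, where 14 of 37 were higher, 3 lower and 20 not called (15 and 4 adjusted over the list alone, camera adjusted p = 3e-05, adjusted p = 0.19 with an estimated correlation). Ctss rose by 2.29 ± 0.22. Border macrophage markers such as Colec12 (-6.13 ± 0.61), Clec12a and Folr2 fell. In that list 3 of 30 were higher, 10 lower and 17 not called (3 and 13 adjusted over the list alone, camera adjusted p = 0.0007, adjusted p = 0.14 with an estimated correlation). For immediate early and dissociation genes 1 of 34 was higher, 12 lower and 21 not called (2 and 15 adjusted over the list alone, camera adjusted p = 0.0072, adjusted p = 0.6 with an estimated correlation). EdgeR called 1758 genes (828 higher and 930 lower at P56), 1865 within batch S232 and 1160 without microglia E14.5 replicate 2, and the DESeq2 Wald test 3022 and limma with library weights 3353. In simulation 51 of 93 limma calls were false against 0 of 37 of edgeR.

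Between successive ages the clearest step in microglia was from P10 to P21, when cell cycle transcripts fell. From E14.5 to P3 (n = 3 each) Angptl7, Sult1a1, Ccl24, Cd74 (230 ± 46.6 against 27.5 ± 3.21 CPM) and Tspan7 (3.14 ± 0.28) rose, and Slc25a24, Igf2bp1, Unc119, Hip1 and the immediate early gene Nr4a1 (-4.53 ± 0.84) fell. From P3 to P10 (n = 3 each) Hspa1a, Ifrd1, Selplg (3151 ± 189 against 552 ± 233 CPM), Serpinf1 and Tmem119 (1.71 ± 0.32) rose and Colec12, Crip1 and Lyz2 were among the falls. Of the microglia markers 5 of 24 were higher, 0 lower and 19 not called (11 and 0 adjusted over the list alone, camera adjusted p = 1.7e-16). From P10 to P21 (3 and 5 libraries) Mctp1, Sult1a1 and Nampt were among the rises. Ulbp1 (at least 358-fold), Efcab11 and Bub1 (-11.51 ± 2.03) led the falls. Of cell cycle genes 0 of 40 were higher, 24 lower and 16 not called (0 and 39 adjusted over the list alone, camera adjusted p = 3.2e-66). In the same step Mrc1 went from 348 ± 23 to 30.9 ± 12.5 CPM (-3.52 ± 0.33) and Apoe from 5568 ± 682 to 1279 ± 1001 (-2.04 ± 0.38). At P21 Apoe was at 1886 to 2176 CPM in S232 but 208 and 170 in S276, so the size of its fall is uncertain. From P21 to P56 (n = 5 each) Mrc1 fell again, to 8.11 ± 4.27 CPM (-1.94 ± 0.29), with Oasl2, Metrnl and Ccr1. The counts were 185, 49, 231 and 10 genes in order of age (140, 35, 40 and 5 of them higher at the later age), and within batch S232 114, 67, 202 and 206. The 185 became 118, 91 and 90 without microglia E14.5 replicates 1, 2 and 3 in turn, and 106 without P3 replicate 4. The 49 became 26, 24 and 27 without microglia P10 replicates 1, 2 and 3, and 25 and 94 without P3 replicates 2 and 3. The 10 became 18 without microglia P21 replicate 5, and 3, 4, 24 and 37 without P56 replicates 2, 3, 4 and 5. EdgeR on the compared groups gave 67, 11, 440 and 1 genes and the DESeq2 Wald test 633, 498, 839 and 699.

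Meningeal macrophages were followed over the same span, and genes of antigen presentation were among their largest gains. H2-Aa, an MHC class II chain gene, went from 0.549 ± 0.269 to 2932 ± 852 CPM (n = 3 each, 12.39 ± 1.55, adjusted p = 4e-07), and Cd74 from 36.9 ± 5.23 to 9437 ± 2687 (8.00 ± 0.74). The largest rises were in H2-Aa, Tnfsf13b, H2-Eb1, Ifi208, Ptgds, Cd209d, Klra2, H2-Ab1, Cd209a, Pla2g2d, Ccl8 and Slamf7. H2-Eb1 reached 2007 ± 694 CPM, the cytokine gene Tnfsf13b (BAFF) was at least 508-fold higher, and Ccl8 went from 0.231 ± 0.18 to 243 ± 68.8. Ptgds, which leptomeningeal cells express strongly, went from 0.58 ± 0.204 to 1023 ± 507 CPM. The largest falls were in Ckap2l, Cdca5, Trim59, Foxm1, Spag5, Ckap2, Kif18b and Angptl4, all without counts at P56, with the mitotic regulator gene Foxm1 at least 870-fold and Ckap2l at least 1650-fold lower. Of MHC class II genes 6 of 11 were higher, 0 lower and 5 not called (9 and 1 adjusted over the list alone, camera adjusted p = 3.1e-22). Of MHC class I genes 9 of 15 were higher, 0 lower and 6 not called (12 and 0 adjusted over the list alone, camera adjusted p = 1.9e-18). Of cell cycle genes 0 of 40 were higher, 25 lower and 15 not called (0 and 35 adjusted over the list alone, camera adjusted p = 1.5e-29). In the dendritic cell list 1 of 15 was higher, 1 lower and 13 not called (5 and 2 adjusted over the list alone, camera adjusted p = 0.022). Its summed level went from 57.7 ± 5.15 to 699 ± 492 CPM, of which Cd209a made up 573 ± 506 at P56, and replicate 1 held 1267 and the others 405 and 425.

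Border macrophage markers rose on balance, as 13 of 30 were higher, 1 lower and 16 not called (16 and 4 adjusted over the list alone, camera adjusted p = 6e-10). Cd209b (7.27 ± 0.73), Cbr2 (2732 ± 258 against 20.9 ± 3.75 CPM) and Cd209f were among them. Microglia markers rose too from a low base, where 14 of 24 were higher, 0 lower and 10 not called (15 and 0 adjusted over the list alone, camera adjusted p = 9.7e-18). Olfml3 was at 208 ± 82.3 against 3.66 ± 1.84 CPM. In complement and Fc receptors 12 of 20 were higher, 0 lower and 8 not called (14 and 0 adjusted over the list alone, camera adjusted p = 7.9e-18). C1qa (2.50 ± 0.12) was an example. Fetal growth and oncofetal genes fell, where 1 of 16 was higher, 7 lower and 8 not called (1 and 7 adjusted over the list alone, camera adjusted p = 0.00025). Igf2bp1 (-9.79 ± 1.96) and H19 were among these. Lysosomal genes rose, as 14 of 37 were higher, 0 lower and 23 not called (17 and 0 adjusted over the list alone, camera adjusted p = 6.3e-10, adjusted p = 0.05 with an estimated correlation). Ctss (3.29 ± 0.24) was among them. Of chemokines and cytokines 7 of 30 were higher, 0 lower and 23 not called (8 and 0 adjusted over the list alone, camera adjusted p = 4.8e-08). Cxcl16 was an example. Of immediate early and dissociation genes 12 of 34 were higher, 1 lower and 21 not called (17 and 1 adjusted over the list alone, camera adjusted p = 1.1e-11, adjusted p = 0.14 with an estimated correlation). Klf4, Socs3 (4.85 ± 0.59) and Atf3 were among these. Apoe went from 11781 ± 508 to 74469 ± 6033 CPM (2.66 ± 0.46). EdgeR called 943 genes (554 higher and 389 lower at P56) and 914 within batch S232, 582 without mMΦ E14.5 replicate 1, 613 without replicate 2, 577 without replicate 3 and 592 without mMΦ P56 replicate 1. Without the libraries that stand apart, none of which is of mMΦ, 1433 were called, with the compared groups alone 1729, with limma and library weights 2674 and with the DESeq2 Wald test 2062.

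The gain of MHC class II transcripts in mMΦ came in steps. From E14.5 to P3 (n = 3 each for every step) Retnla (213 ± 176 against 0.0927 ± 0.0944 CPM), Ptgds, Ccl8, Cd209g and Cbr2 (5.36 ± 0.68) rose, Cd163 went from 71.7 ± 3.07 to 920 ± 56.2 CPM (3.68 ± 0.46), and Phgdh, Lpl and Egr1 were among the falls. Of immediate early and dissociation genes 0 of 34 were higher, 10 lower and 24 not called (1 and 21 adjusted over the list alone, camera adjusted p = 1.6e-41). From P3 to P10 Gadd45g, H2-Aa (58.1 ± 26.5 against 1.06 ± 0.119 CPM), H2-Eb1, H2-Ab1 and Atf3 (4.68 ± 0.56) rose and Brca1 and Stab1 fell. For MHC class II in that step 5 of 11 were higher, 0 lower and 6 not called (6 and 1 adjusted over the list alone, camera adjusted p = 3e-13). For immediate early and dissociation genes 22 of 34 were higher, 0 lower and 12 not called (31 and 0 adjusted over the list alone, camera adjusted p = 2.2e-86). The sum of the latter in mMΦ at P3 was 13437 CPM in replicate 3 and 3484 and 3277 in the other libraries. From P10 to P21 the adhesion molecule gene Vcam1 (519 ± 116 against 50.8 ± 13.4 CPM), Tsc22d3, Tagap, Tmem119 and Lair1 rose. From P21 to P56 H2-Ab1 (3836 ± 1467 against 192 ± 117 CPM), Cd74 (3.91 ± 0.61), Dph5, H2-DMa and H2-DMb1 rose. Of MHC class II genes 4 of 11 were higher, 0 lower and 7 not called (6 and 1 adjusted over the list alone, camera adjusted p = 7.7e-16). The counts were 114, 114, 15 and 17 genes in order of age (86, 109, 15 and 7 higher at the later age) and within batch S232 141, 127, 12 and 19. The first 114 became 68 without mMΦ E14.5 replicate 1, 71 without replicate 3, 75 without mMΦ P3 replicate 1 and 71 without replicate 2, and the second 75 without mMΦ P10 replicate 3, 59 without mMΦ P3 replicate 1 and 59 without replicate 2. The 15 became 6 without mMΦ P10 replicate 1, 4 without replicate 2 and 7 without replicate 3, and the count of 17 became 9 without mMΦ P21 replicate 2, 26 without replicate 3 and 28 without mMΦ P56 replicate 3. With the compared groups alone the steps held 1629, 1034, 10 and 0 genes (497 in the last at an unadjusted p under 0.05), with limma and library weights 1938, 1305, 110 and 55, and with the DESeq2 Wald test 444, 397, 292 and 735.

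Perivascular macrophages, followed from P10 to P56 (3 and 4 libraries), gained MHC class II transcripts as well. H2-Aa went from 19.4 ± 24.4 to 2827 ± 955 CPM (7.26 ± 1.24, adjusted p = 0.00037). Of MHC class II genes 6 of 11 were higher, 0 lower and 5 not called (6 and 0 adjusted over the list alone, camera adjusted p = 2.7e-15). The summed dendritic cell markers went from 114 ± 6.85 to 638 ± 293 CPM, mostly by Cd209a (2.63 ± 3.03 to 439 ± 244), and the list was not called (camera adjusted p = 0.12). The largest rises were in Klra2 (at least 281-fold), Csmd3, Cd209a, H2-Aa, H2-Ab1, H2-Eb1, Cd74 (4.74 ± 0.63), Cd209b, Ptgds, Mt2 and Socs3 (262 ± 74.1 against 15.5 ± 1.85 CPM). The largest falls were in Rtel1, Fmo1, Dna2, Neil3, Sgo2a, Oip5, Pimreg, Dnai1 and Cdc20 (0.0347 ± 0.0418 against 77.2 ± 2.88). Cell cycle genes fell, as 0 of 40 were higher, 11 lower and 29 not called (0 and 24 adjusted over the list alone, camera adjusted p = 2.3e-21). Of immediate early and dissociation genes 24 of 34 were higher, 0 lower and 10 not called (26 and 0 adjusted over the list alone, camera adjusted p = 3.3e-32). Atf3 (3.41 ± 0.52), Dusp1 and Klf4 rose, and the sum went from 9185 ± 883 to 44308 ± 7959 CPM. Complement and Fc receptor genes rose, where 8 of 20 were higher, 0 lower and 12 not called (12 and 1 adjusted over the list alone, camera adjusted p = 2.5e-09), with Itgb2, Fcgr2b and C1qb, and of microglia markers 5 of 24 were higher, 0 lower and 19 not called (6 and 0 adjusted over the list alone, camera adjusted p = 5.7e-09, adjusted p = 0.06 with an estimated correlation), with Selplg, Cst3, Siglech and Tmem119. The class II gain had begun by P21, as 6 of 11 were higher, 0 lower and 5 not called (6 and 0 adjusted over the list alone, camera adjusted p = 3e-12) between P10 and P21. Their sum was 464 ± 105 CPM at P10 and at P21 8559 in replicate 1, which stood apart, and 1294, 2956 and 4139 in the others. Without the libraries that stand apart 4 of 10 were higher, and with the compared groups alone 0. H2-Eb1, H2-Ab1 (5.04 ± 0.81), H2-Aa, Ccr2 and Vcam1 (596 ± 91.7 against 37.9 ± 15 CPM) were the largest rises of that step, with Kif18b, Mastl and Pif1 among the falls. From P21 to P56 (n = 4 each) Eif4g1, Ier5, Pmepa1, H2-DMb1 and the lysozyme gene Lyz2 (17112 ± 3332 against 8119 ± 2940 CPM) rose.

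For pvMΦ, edgeR called 450 genes from P10 to P56 (202 higher and 248 lower at P56), 104 from P10 to P21 (64 and 40) and 45 from P21 to P56 (14 and 31), and within batch S232 746, 104 and 379. These counts rested on few libraries. Replicate 4 was the only S276 library of pvMΦ at P56, so its effect on the counts cannot be told from that of the batch. The 450 became 245 without pvMΦ P10 replicate 1, 202 without replicate 2, 204 without replicate 3, 294 without pvMΦ P56 replicate 1, 258 without replicate 3 and 818 without replicate 4. The 104 became 31 without pvMΦ P10 replicate 1, 20 without replicate 2, 33 without replicate 3, 36 without pvMΦ P21 replicate 1, 46 without replicate 2 and 159 without replicate 3. The 45 became 123 without pvMΦ P21 replicate 4, 8 without pvMΦ P56 replicate 1, 9 without replicate 3 and 416 without replicate 4. With the compared groups alone 131, 9 and 0 genes were called (388 in the last at an unadjusted p under 0.05), with limma and library weights 817, 354 and 18 and with the DESeq2 Wald test 1587, 557 and 1341. In simulation 12 of 51 calls from P10 to P56 were false (16341 genes).

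**Figure D4:**
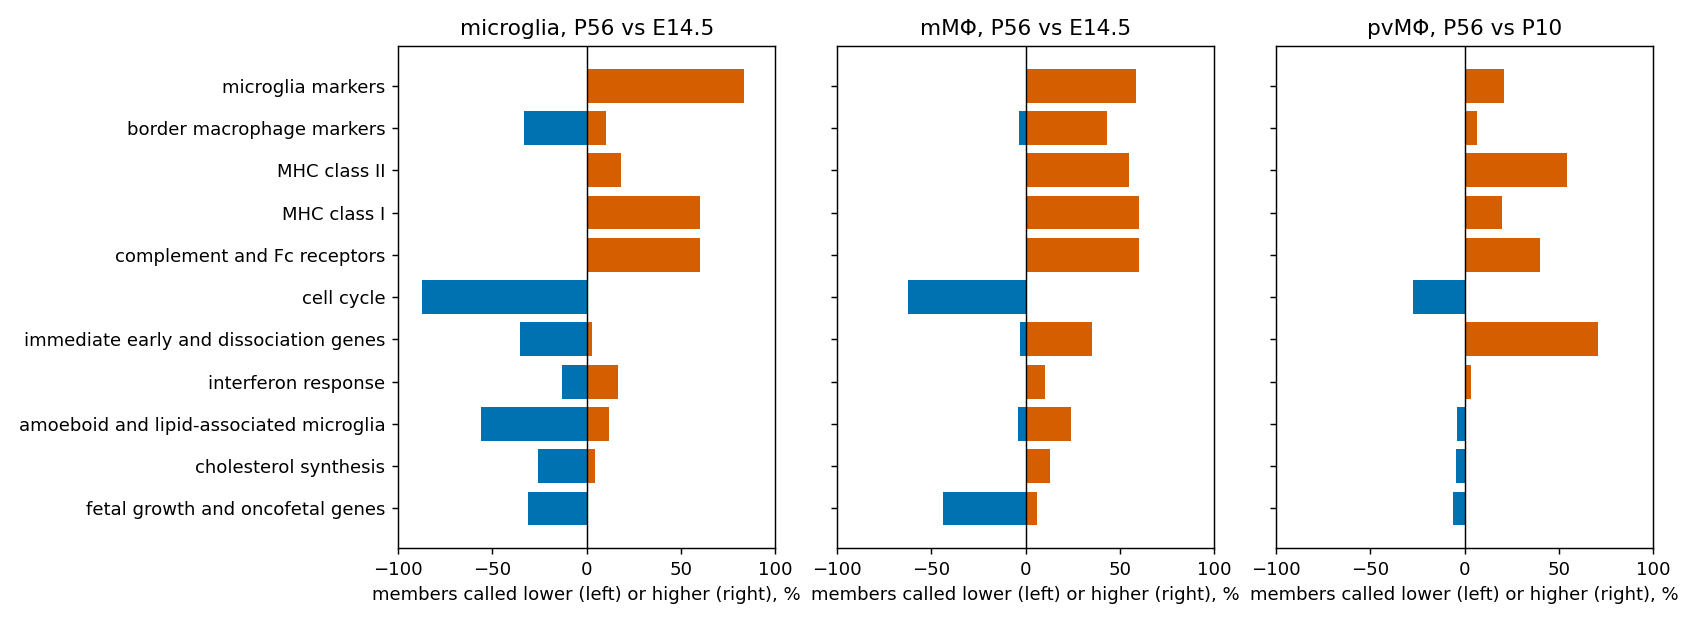
Members of 11 gene lists called lower (blue, left of 0) or higher (orange, right of 0) at the later age, as a percentage of the members tested, in microglia (P56 against E14.5), mMΦ (P56 against E14.5) and pvMΦ (P56 against P10). Of 40 cell cycle genes, 35, 25 and 11 were lower, and of 11 MHC class II genes, 2, 6 and 6 were higher.

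Whether the populations changed differently with age was tested on the difference of their changes. From E14.5 to P56, mMΦ gained relative to microglia in 213 genes and lost in 81 (294 in all). By camera p, border macrophage and immediate early and dissociation genes led the lists of this divergence. Itgb7, Crabp1, Mcemp1, Cd209a, Pdlim7, Ccn1, H2-Aa (12.39 ± 1.65), Plbd1, Cyp4f18, Bhlhe40 and Hopx gained most and Vangl1, Angptl7, Slc39a12 and Adora3 lost most. Apoe diverged by 6.68 ± 0.64, since it rose in mMΦ and stood at 330 ± 103 CPM in microglia at P56 against 7613 ± 592 at E14.5. In the border macrophage list 14 of 30 were higher, 1 lower and 15 not called (19 and 1 adjusted over the list alone, camera adjusted p = 1.1e-23). In MHC class II 6 of 11 were higher, 0 lower and 5 not called (7 and 1 adjusted over the list alone, camera adjusted p = 2.9e-15), in the amoeboid and lipid-associated list 10 of 25 were higher, 0 lower and 15 not called (15 and 1 adjusted over the list alone, camera adjusted p = 2.1e-20). In cholesterol synthesis 7 of 23 were higher, 0 lower and 16 not called (10 and 0 adjusted over the list alone, camera adjusted p = 5.6e-15). In the immediate early and dissociation list 15 of 34 were higher, 0 lower and 19 not called (22 and 0 adjusted over the list alone, camera adjusted p = 2.4e-23). From P10 to P56, pvMΦ gained relative to microglia in 80 genes and lost in 14 (94 in all). Epdr1, Cenpf, Vav3, Gpx3 (7.91 ± 0.74), Pgap6, Cd74 (7.15 ± 0.79), H2-Ab1, H2-Aa, Bcl3, Folr2 and Mrc1 (5.46 ± 0.49) were the largest gains and Zfp951, Dcun1d3 and Wdr5b the largest losses. For immediate early and dissociation genes 19 of 34 were higher, 0 lower and 15 not called (28 and 0 adjusted over the list alone, camera adjusted p = 2e-42). Between pvMΦ and mMΦ the changes from P10 to P56 differed in 12 genes, 11 of them gains in pvMΦ. Among these were Angptl7, Mtrf1, Mylip, Rgs2 (1.98 ± 0.30), the LPS co-receptor gene Cd14 (1.97 ± 0.36), Atf4, Rhob, Srsf5, Zfp36l1 and the costimulatory gene Cd86 (1.38 ± 0.24), with Vps35l the single loss. Immediate early and dissociation genes moved the same way, from 9185 to 44308 CPM in pvMΦ and from 38345 to 62218 in mMΦ.

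The tests of divergence between mMΦ and microglia called 384 genes within batch S232, between pvMΦ and mMΦ 83, and between pvMΦ and microglia 302. The 294 became 180 without mMΦ E14.5 replicate 1, 171 without replicate 2 and 181 without replicate 3. The 12 became 5 without mMΦ P10 replicate 2, 6 without replicate 3, 20 without mMΦ P56 replicate 3, 5 without pvMΦ P10 replicate 1, 5 without replicate 2, 7 without replicate 3, 5 without pvMΦ P56 replicate 3 and 127 without replicate 4. The 94 became 61 without microglia P10 replicate 2, 61 without replicate 3, 40 without pvMΦ P10 replicate 1, 33 without replicate 2, 36 without replicate 3 and 252 without pvMΦ P56 replicate 4. With the compared groups alone the tests gave 454, 109 and 58 genes, with limma and library weights 760, 76 and 91 and with the DESeq2 Wald test 1101, 671 and 807. Regrouped libraries reached the counts of the compared groups in 3, 2 and 3 of 30 splits. These can turn a difference into an average effect and do not decide on chance.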

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

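The tests of microglial RNA in pvMΦ, of dendritic cells in mMΦ, of class II genes against all other genes and of the spread of fold changes were chosen only after the results they bear on were seen; the tests of batch, of scaling, of the number of libraries and of regrouped libraries were written before.

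A library far from the others of its group flagged 5 of 68 tests of single genes in groups of 4 or 5, where chance flags about 1 in 20 (3.4). Pf4 was at 4.36 CPM in microglia P56 replicate 2, with the nearest other library at 1.67. Lyve1 was at 1967 CPM in pvMΦ P21 replicate 3 (nearest 658), which of the P21 libraries held the lowest share of microglial transcripts. H2-Aa was at 19.6 CPM in microglia P56 replicate 3 (nearest 3.31). Mki67 was at 1.5 CPM in microglia P21 replicate 3 (nearest 0.109) and at 0.606 in microglia P56 replicate 2 (nearest 0.114).

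A difference between populations in their change with age, tested directly, flagged 294 genes for mMΦ against microglia from E14.5 to P56. Among the genes followed throughout these were Mrc1 (3.85 in log2), Cd163 (4.12), Ms4a7 (6.13), H2-Aa (12.39), Cd74 (7.56), Cx3cr1 (-1.54) and Apoe (6.68). From P10 to P56 it flagged 12 genes for pvMΦ against mMΦ, and 94 for pvMΦ against microglia, with Mrc1 (5.46), H2-Aa (5.91), Cd74 (7.15) and Apoe (4.77) among them.

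Microglial transcripts were higher in pvMΦ than in mMΦ, which could reflect microglia or their RNA in the pvMΦ sort, or a shared programme of cells within the parenchyma. A mixed-in share would bring every gene abundant in microglia and nearly absent from mMΦ to the same share of its microglia level. At P56, 80.8% of such genes lay within 2-fold of the median share, just past the 80% set for this explanation, so it remains open and fits; at P10 it was 95% and at P21 76.2%. The sequencing batch did not account for it, since 13 microglia markers were still higher at P56 within batch S232. The median share was 5.9 to 14% in 3 of the P56 libraries and 0.0421% in replicate 3, which stood apart; that library still held 38480 CPM of microglia markers against 24440 to 28519 in mMΦ, which a share near 0 would not give.

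MHC class II genes were higher in mMΦ at P56 than at E14.5, which could reflect maturation or dendritic cells among the sorted cells. If dendritic cells brought them, dendritic cell markers and MHC class II genes should differ between pvMΦ and mMΦ by the same ratio, and their ratio of ratios was 1.05 (0.911 to 1.46 with 1 library left out). Both ratios were near 1 (0.914 and 0.872), as any source would give, so the test does not decide and dendritic cells stay open. Most of the marker sum was Cd209a, which border macrophages may express themselves, at 573 of 699 CPM. With the other scaling 6 MHC class II genes were still called, but it moved fold changes by only 0.043. Composition shifts all genes alike, and the class II list rose against all other genes (camera adjusted p = 7.1e-08 with an estimated correlation), which argues against it.

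More genes differed between mMΦ and microglia at P56 than at E14.5, which could reflect divergence or a difference in precision between ages. The prediction written before took the spread of fold changes shared by disjoint libraries as the measure; at 1.65 times the E14.5 value it met the outcome set against the precision explanation. That prediction was wrong for counts, because it measures the size of fold changes, and 2 fits that give comparisons or libraries their own scatter turned the order of the counts (2432 to 711 and 2772 to 2038), so precision fits the counts, a verdict settled after the result was seen. For the spread itself the same value of 1.65 (1.6 to 1.7 with libraries left out) speaks against precision and for fold changes that widened with age. The number of libraries did not account for the count, which was 1890 at P56 with batch S232 only.

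Libraries were regrouped to ask how often chance alone gives as many calls, with edgeR on the compared groups. Dropping repeated splits and making fewer draws for the differences of changes was decided after earlier splits were seen. For mMΦ against microglia the real grouping gave 1224 at P21 and 711 at P56, each 1 of 46 splits (highest other 189 and 124). For genes shared by all 5 ages it gave 272, 1 of 100 (highest other 0). As other splits at E14.5, P3 and P10 gave 0, the 1 of 100 does not decide. For pvMΦ against microglia it gave 891 at P21, as many as 2 of 100 splits (highest other 1432, with all S276 libraries on 1 side), and 465 at P56, 1 of 100 (highest other 211). For pvMΦ against mMΦ it gave 0 at P21 and P56 (25 of 25 splits, highest other 14 and 0), and since every split reaches 0 this says nothing about chance. With age it gave 1949 in microglia over the whole span, 1 of 46 (highest other 742), 131 in pvMΦ, 1 of 25 (highest other 0), 440 in microglia from P10 to P21, 1 of 46 (highest other 3), and 1 from P21 to P56, reached by 4 of 100 (highest other 1231). In pvMΦ it gave 9 from P10 to P21, reached by 2 of 25 (highest other 593), and 0 from P21 to P56 (35 of 35, highest other 3), which again says nothing. The differences of changes gave 454 (mMΦ against microglia), 109 (pvMΦ against mMΦ) and 58 (pvMΦ against microglia). As many came in 3, 2 and 3 of 30 (highest other 625, 123 and 127). A split can turn a difference into an average effect, so these do not decide on chance. Splits with many more calls than the real one point to another structure among the libraries. In the comparisons of 3 with 3 libraries the real grouping gave 2432, 1354 and 2927 (mMΦ against microglia at E14.5, P3 and P10), 2166 and 538 (pvMΦ against microglia and mMΦ at P10), 1729 (mMΦ over the whole span), 67 and 11 (first 2 microglia steps) and 1629, 1034, 10 and 0 (mMΦ steps), with 1 of 10 splits as large (10 of 10 for the last) and 0 as the highest other, and 10 splits are too few to exclude chance.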

How the results depend on the processing

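No named gene turned its direction under any setting, but the rise of the counts of mMΦ against microglia with age turned in 2 of them. Size factors in place of TMM moved no count by over 1.5 times, and the largest median shift of all fold changes was 0.064. Of the values of named genes, 627 of 632 kept their direction and their call with size factors, 630 with the DESeq2 Wald test, 536 without the low-count filter, 568 without the batch term, 550 with batch S232 only, 454 with limma voomWithQualityWeights, 594 without the libraries that stand apart, 451 of 615 with the groups compared only, and 4048 of 4948 with 1 library left out, and all others kept their direction but were no longer called. Camera gave 361 calls, 180 with an estimated correlation and 325 without members shared by lists. The cause of the movements that follow was not tested, except where the setting's own construction gives it. The depth limits claims on genes with few counts, and 3 to 5 libraries per group limit all comparisons.

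With the DESeq2 Wald test 28 counts moved: mMΦ against microglia 931 (E14.5), 1702 (P3), 2058 (P10), 2806 (P21), 3617 (P56), pvMΦ against microglia 1394 (P10), 2802 (P21), 3507 (P56), pvMΦ against mMΦ 324 (P10), 780 (P21), 1463 (P56), microglia 3022 (P56 against E14.5), 633 (P3 against E14.5), 498 (P10 against P3), 839 (P21 against P10), 699 (P56 against P21), mMΦ 2062 (P56 against E14.5), 444 (P3 against E14.5), 397 (P10 against P3), 292 (P21 against P10), 735 (P56 against P21), pvMΦ 1587 (P56 against P10), 557 (P21 against P10), 1341 (P56 against P21), 1101 (change mMΦ against microglia), 671 (change pvMΦ against mMΦ), 807 (change pvMΦ against microglia), 428 (all 5 ages). With limma voomWithQualityWeights (chosen after the data were seen) 24 counts moved: mMΦ against microglia 2772 (E14.5), 1839 (P3), 3884 (P10), pvMΦ against microglia 2962 (P10), 1052 (P56), pvMΦ against mMΦ 893 (P10), 32 (P21), 17 (P56), microglia 3353 (P56 against E14.5), 421 (P3 against E14.5), 141 (P10 against P3), 905 (P21 against P10), 26 (P56 against P21), mMΦ 2674 (P56 against E14.5), 1938 (P3 against E14.5), 1305 (P10 against P3), 110 (P21 against P10), 55 (P56 against P21), pvMΦ 817 (P56 against P10), 354 (P21 against P10), 18 (P56 against P21), 760 (change mMΦ against microglia), 76 (change pvMΦ against mMΦ), 620 (all 5 ages). With edgeR on the groups compared only 24 counts moved: mMΦ against microglia 2432 (E14.5), 1354 (P3), 2927 (P10), 711 (P56), pvMΦ against microglia 2166 (P10), 891 (P21), 465 (P56), pvMΦ against mMΦ 538 (P10), 0 (P21), 0 (P56), mMΦ 1729 (P56 against E14.5), 1629 (P3 against E14.5), 1034 (P10 against P3), 0 (P56 against P21), pvMΦ 131 (P56 against P10), 9 (P21 against P10), 0 (P56 against P21), microglia 67 (P3 against E14.5), 11 (P10 against P3), 440 (P21 against P10), 1 (P56 against P21), 454 (change mMΦ against microglia), 109 (change pvMΦ against mMΦ), 58 (change pvMΦ against microglia). Without the low-count filter, where more genes are adjusted for, 12 counts moved: mMΦ against microglia 492 (P3), 740 (P10), pvMΦ against mMΦ 33 (P21), 59 (P56), microglia 1144 (P56 against E14.5), 107 (P3 against E14.5), mMΦ 542 (P56 against E14.5), 8 (P21 against P10), pvMΦ 213 (P56 against P10), 46 (P21 against P10), 191 (change mMΦ against microglia), 51 (change pvMΦ against microglia). Without the batch term 7 counts moved: pvMΦ against mMΦ 61 (P56), pvMΦ 297 (P56 against P10), 66 (P21 against P10), 20 (P56 against P21), microglia 123 (P3 against E14.5), 30 (P10 against P3), mMΦ 8 (P21 against P10). With batch S232 only 7 counts moved: pvMΦ against mMΦ 288 (P56), pvMΦ 746 (P56 against P10), 379 (P56 against P21), microglia 114 (P3 against E14.5), 206 (P56 against P21), 83 (change pvMΦ against mMΦ), 302 (change pvMΦ against microglia). Without the libraries that stand apart (chosen after the data were seen) 11 counts moved: pvMΦ against mMΦ 174 (P56), mMΦ 1433 (P56 against E14.5), 195 (P3 against E14.5), 23 (P21 against P10), 42 (P56 against P21), microglia 286 (P3 against E14.5), 98 (P10 against P3), 399 (P21 against P10), pvMΦ 67 (P21 against P10), 28 (P56 against P21), 21 (change pvMΦ against mMΦ).

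With 1 library left out, which leaves fewer libraries in a group, counts moved in 21 comparisons, with ranges of 507 to 657 (mMΦ against microglia at P3), 721 to 807 (mMΦ against microglia at P10), 423 to 487 (pvMΦ against microglia at P10), 53 to 71 (pvMΦ against mMΦ at P10), 33 to 145 (pvMΦ against mMΦ at P21), 41 to 398 (pvMΦ against mMΦ at P56), 1160 to 1754 (microglia P56 against E14.5), 577 to 746 (mMΦ P56 against E14.5), 202 to 818 (pvMΦ P56 against P10), 90 to 213 (microglia P3 against E14.5), 24 to 94 (microglia P10 against P3), 3 to 37 (microglia P56 against P21), 68 to 119 (mMΦ P3 against E14.5), 59 to 99 (mMΦ P10 against P3), 4 to 16 (mMΦ P21 against P10), 9 to 28 (mMΦ P56 against P21), 20 to 159 (pvMΦ P21 against P10), 8 to 416 (pvMΦ P56 against P21), 171 to 317 (change mMΦ against microglia), 5 to 127 (change pvMΦ against mMΦ), 33 to 252 (change pvMΦ against microglia). The counts of mMΦ against microglia at E14.5, P21 and P56, of pvMΦ against microglia at P21 and P56, of microglia from P10 to P21 and of genes shared by all 5 ages stayed within 1.5 times.

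With the replicate number as a replicate block 8 counts moved: mMΦ against microglia 314 (P3), 1052 (P21), 1435 (P56), pvMΦ against microglia 973 (P21), 1155 (P56), pvMΦ against mMΦ 35 (P21), microglia 16 (P56 against P21), mMΦ 11 (P56 against P21). Of named genes' values 509 of 632 kept their call. Mice of different groups share only a number: of 34 same-numbered pairs 2 had a correlation over 0.1 (median -0.007), and of 105 other pairs 6 (median -0.001), so the libraries were not taken as paired.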

Other observations

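Spic, a factor of iron-recycling macrophages, was at 37.1 ± 19 CPM in mMΦ and 43.2 ± 14.1 in pvMΦ at P56 against 0.0114 ± 0.0255 in microglia (log2 fold changes 10.89 ± 1.70 and 11.16 ± 1.67), and Ahr at 6.85 ± 5.42 and 35.9 ± 35 against 0.103 ± 0.173. Spi1 was at 434 ± 63.7 CPM in mMΦ and 532 ± 88.3 in microglia at P56 and was not called. Of 43 macrophage transcription factors 10 were higher, 2 lower and 31 not called (14 and 2 adjusted over the list alone, camera adjusted p = 4.9e-07) in pvMΦ from P10 to P56. In mMΦ from E14.5 to P56, 8 were higher, 0 lower and 35 not called (14 and 0 over the list alone, camera adjusted p = 9.1e-06). Klf4 (5.01 ± 0.62) and Klf6 rose, but Klf4 is also of the immediate early and dissociation list, which rose too, so handling stays open. Vcam1 rose in mMΦ from 13.9 ± 3.91 to 412 ± 103 CPM (4.89 ± 0.75).

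Of markers of astrocytes and radial glia at P56 7 of 21 were higher, 1 lower and 13 not called (13 and 2 adjusted over the list alone, camera adjusted p = 0.00058) in mMΦ against microglia, and 6 of 21 were higher, 1 lower and 14 not called (10 and 2 adjusted over the list alone, camera adjusted p = 0.0041) in pvMΦ, but their sums were 273 ± 127, 275 ± 133 and 202 ± 64 CPM in mMΦ, microglia and pvMΦ, so not higher in total. Between mMΦ and microglia 5237 genes (30.7% of those tested) had no overlap between libraries at E14.5, where chance gives 10%, and 2266 (13.3%) at P56, where chance gives 3.57%. Between pvMΦ and mMΦ 20.1% of genes at P10 had none, against 10% by chance, and 5.8% at P21 and 4.3% at P56, against 5.71% by chance. Immediate early and dissociation genes summed to 23000 CPM in microglia P21 replicate 4 and 18343 in replicate 5, both of batch S276, and to 4538 to 7634 in the other 3.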
